A study of Rattus norvegicus with 18 samples.

How the data were processed

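Gene expression was measured in total RNA of whole rat kidney on spotted cDNA arrays, each hybridised with 2 samples labelled with Cy3 and Cy5. The samples came from 12 rats, 6 sham-operated and 6 that had gone through 52 min of renal ischemia followed by reperfusion and 35 days of recovery, here called ARF rats after the acute renal failure that this injury causes. The labels name 6 pairs, A to F, of 1 sham and 1 ARF rat. Each pair was hybridised on 2 arrays with the dyes exchanged, which gave 12 arrays, and 6 further arrays, R1 to R6, compared sham rats with one another. Rats, not arrays, were the replicates: the 2 arrays of a pair hold the same 2 RNAs and were averaged to 1 value.

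The deposited values are normalized log values, per the labels, which name ImaGene 4.1 as the source of the raw data and cite an earlier method for spot quality, detection and the adjustment of weak signals. The deposited unit is a log ratio of the 2 channels whose log base is not given in the sources used here. Empty cells made up 57.1% of the table, which was taken as the authors' filter on spots, and 0 values were exactly 0. Every array had a mean of 0, so the deposited values are centred on the mean of each array. The medians of the arrays with sham in Cy3 were -0.039, -0.004, -0.026, 0.029, -0.011 and -0.033 for pairs A to F, those with sham in Cy5 were 0.003, -0.028, -0.013, -0.042, -0.024 and -0.012, and those of the sham-sham arrays R1 to R6 were -0.005, -0.036, 0.011, -0.011, 0.003 and 0.006. The log base and the direction of the ratio stay unknown from the labels. Across clones the 2 dye orientations of a pair correlated above 0 in all 6 pairs (r from 0.196 to 0.58), so the authors were taken to have turned both the same way before deposit. Under the rule fixed before the data were examined, channel 2 over channel 1, a positive value then means higher in ARF; this direction is assumed, and no value in the table tests it.

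The table has 4608 rows. The 1519 accessions listed on 2 rows all lay 1152 rows apart, so the rows were read as 2304 clones spotted in duplicate, and the 2 spots were averaged. Duplicate spots correlated with r between 0.60 and 0.904 within an array. Names came from the platform's annotation, updated by gene identifier through a RefSeq gene table for GRCr8: 1489 clones had 1 gene symbol, of which 1483 matched, 32 had several and 783 had none. Clones with several symbols or none were tested but not named. No coordinates are given, because no genome build belongs to the array values.

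The sham-sham columns held values on other rows than the 12 ARF-sham columns. A search over block sizes found that exchanging adjacent blocks of 288 rows brought the 2 kinds of array together: the mean correlation of where values were present went from -0.011 to 0.488. The sham-sham columns were put in that order wherever a gene is named or arrays are compared clone by clone. The exchange was chosen after the values were seen, and counts of clones within the sham-sham arrays do not depend on it.

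For ARF against sham, the 6 pair values of each clone were tested against 0 with limma (an intercept, moderated by eBayes; R 4.3.3, limma 3.58.1), for clones with both arrays in at least 4 pairs, and Benjamini-Hochberg adjusted p under 0.05 was the threshold. The pairing comes from the labels. The sham-sham arrays were tested in the same way, with values on at least 4 arrays; here arrays, which share rats, stood in for replicates. The dye effect was the difference between the 2 arrays of a pair, divided by 2. The SD of the log ratios per array was compared with a two-sided exact permutation test, which treats arrays that share sham rats as independent. Gene lists fixed before the data were examined were tested with limma's camera method at a preset correlation of 0.01 on 1 value per gene, written to allow empty cells, for lists with at least 3 measured genes. An estimated correlation was an alternative. It also used the residual degrees of freedom of the 6 pairs instead of those over genes, which by itself raises p. The 24 lists covered injury and repair, matrix and fibrosis, macrophages and antigen presentation, lymphocytes, chemokines, complement and acute phase, proximal tubule, loop and distal tubule, collecting duct, podocytes and mesangium, endothelium, smooth muscle, vasoactive systems, fatty acid oxidation, oxidative phosphorylation, antioxidants, heat shock, proliferation, apoptosis, growth factors, erythrocytes, skeletal muscle and adipocytes, neurons, and ribosomal proteins. The procedure was tested on simulated data for ARF against sham, with 947 clones and 60 changed in each of 20 simulations. It recovered 55.8% of clones shifted by 0.3, 95% of those shifted by 0.6 and 99.2% of those shifted by 1. Of its calls 5.21% were false. The simulated clones varied independently, and each shift was the same in all 6 pairs. The real pairs correlated with one another at r from -0.227 to 0.669 over clones, so these rates need not hold for the data.

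Genes named are, by a rule fixed before the data were examined, up to 12 clones with the highest and 12 with the lowest mean among those past the threshold with 1 sign in every measured pair, up to 4 members of each list with the largest absolute mean (those past the threshold first), 22 genes set in advance, and, where fewer than 10 clones pass, the 10 with the smallest unadjusted p. Adjusted p-values of single genes are over clones, and those behind list counts are over genes; only 1 gene had several tested clones, and their signs did not differ. Alternatives covered the test, the replicate block, centring and scaling, missing values, the dye orientation, and the leaving out of each pair or array. The number of arrays limits the precision of every value.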

Results

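The kidneys of 6 sham-operated rats and 6 rats that had recovered for 35 days from 52 min of ischemia (ARF rats) were compared pairwise on 12 two-colour cDNA arrays, and 6 arrays compared sham rats with one another. The ARF-sham arrays held values for 1586 to 2786 of the 4608 spots and the sham-sham arrays for 914 to 2232. Of 2304 clones, 947 had both dye orientations in at least 4 pairs and were tested, among them 600 measured in all 6 pairs.

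The first comparison asked which kidney genes still differ from sham levels weeks after the injury. S100a4, a calcium-binding protein of fibroblasts and migrating cells, was higher in ARF kidneys with a log ratio of 0.70 ± 0.23 (SD, n = 4 pairs). Col1a1, a chain of the fibrillar collagen of scar tissue, was higher by 0.53 ± 0.21 (n = 4). Lower were Rbp4, the carrier of retinol (-0.78 ± 0.40, n = 6), the small heat shock protein Cryab (-0.61 ± 0.32, n = 6), the cyclin Ccnd1 (-0.56 ± 0.16, n = 6), the growth factor Egf, made by the distal tubule (-0.34 ± 0.16, n = 6), the clock-controlled transcription factor Dbp (-0.33 ± 0.13, n = 6) and the fatty acid-binding protein Fabp3 (-0.31 ± 0.12, n = 6). Each of these had 1 sign in every pair measured on both arrays. With pairs measured on 1 array kept, S100a4 had 0.56 (n = 5, adjusted p = 0.12) and Col1a1 0.36 (n = 6, adjusted p = 0.19), and neither passed. Egf, Dbp and Fabp3 kept their values there but did not pass either (adjusted p = 0.081 each), while Ccnd1, Rbp4 and Cryab did. The direction is not stated by the labels and is assumed here from the channel convention fixed in advance, channel 2 over channel 1, which no value tests. With the opposite convention every sign would turn. The log base is not stated either, and a difference of 0.5 is 1.41-fold if the base is 2, 1.65-fold for natural logs and 3.16-fold for base 10.

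**Figure D1:**
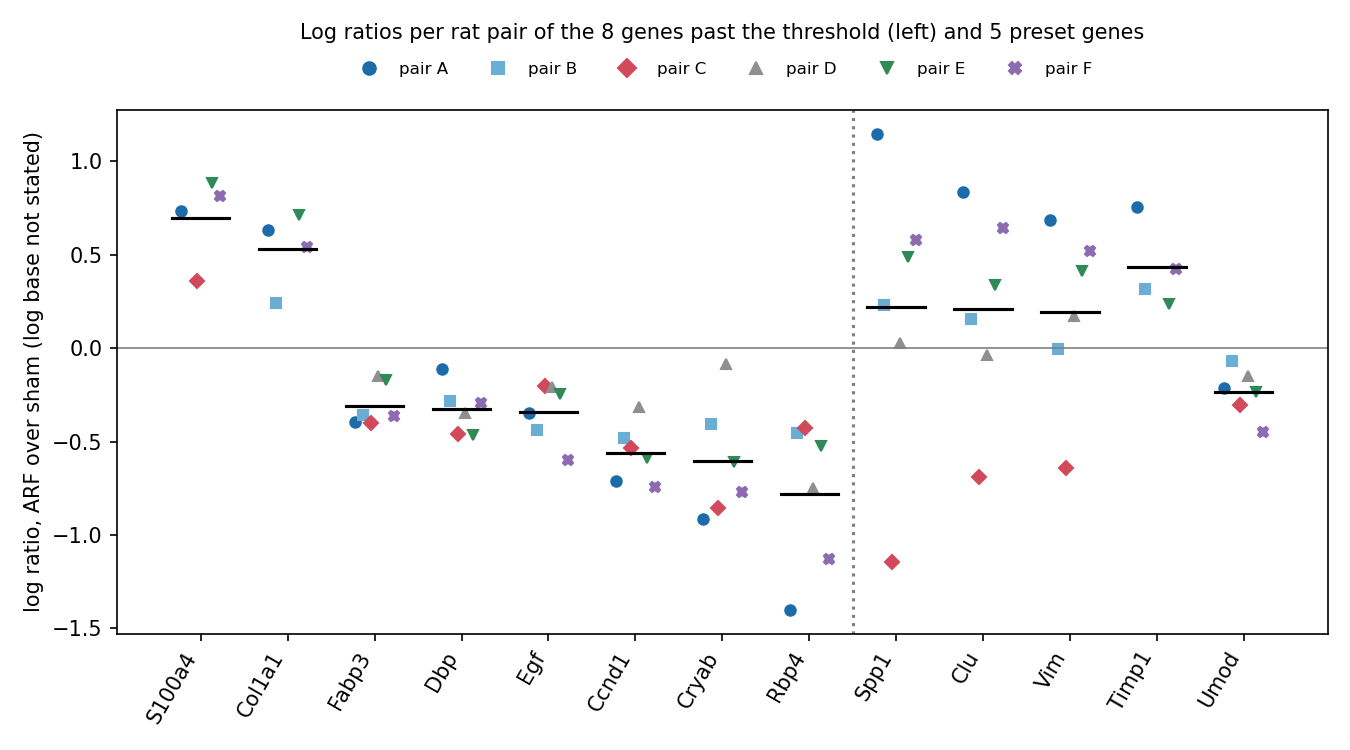
Log ratio of ARF over sham (vertical axis, log units of unstated base) in each rat pair for the 8 genes past the threshold, left of the dotted line, and 5 genes set in advance; points are pairs and black bars are means over pairs. Spp1 lay at 1.15 in pair A and at -1.15 in pair C, while Ccnd1 lay below 0 in all 6 pairs.

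Of the 947 clones, 9 passed the threshold (limma, Benjamini-Hochberg adjusted), 3 higher and 6 lower in ARF, and 139 had an unadjusted p under 0.05. The adjusted p was 0.0063 for Ccnd1, 0.028 for S100a4 and Rbp4, 0.034 for Cryab and 0.048 for Col1a1, Egf, Dbp and Fabp3. The ninth clone carries several gene symbols. St6gal1, a sialyltransferase, did not pass, at -0.38 ± 0.21 (n = 6, adjusted p = 0.0502). On the sham-sham arrays Egf lay between 0.0041 and 0.106 and Ccnd1 between -0.34 and -0.019, while S100a4 reached -0.50, Rbp4 -0.54, Cryab 0.43 and Col1a1 0.49. In size this value of Col1a1, from array R2, is close to its mean for ARF. Its sign only follows which sham rat was in channel 2. Arrays R1, R5 and R6 gave 0.13, 0.032 and -0.013 for Col1a1. Fabp3 reached 0.28 and Dbp 0.24, against means for ARF of -0.31 and -0.33. Cryab and Fabp3 also had a dye effect past the threshold (0.24 and 0.12), which cancels in the mean of the 2 orientations. Centred on array medians, 16 clones passed, 9 higher and 7 lower, and a fit of all 12 arrays with the pair as a replicate block gave 42. With a dye term added to that fit 29 passed, without Col1a1 (adjusted p = 0.096). The 2 arrays of a pair were taken to correlate at 0.29 in the first of these fits and at 0.51 with the dye term. Both fits thus count the 2 arrays of the same rats in part as separate replicates. With no replicate block, on 12 rat levels, 3 of 565 passed, without Dbp (adjusted p = 0.24), Egf (0.13) and Fabp3 (0.23), while S100a4, Col1a1 and Rbp4 could not be tested. Centred per block of rows 5 passed, again without Dbp (adjusted p = 0.072), Egf (0.065) and Fabp3 (0.054). No clone passed with the unmoderated test (129 at an unadjusted p under 0.05), with limma's trend and robust options (119), or without pair E (68) or pair F (59); 1 passed without pair B, 4 without pair A, 19 without pair C and 18 without pair D. With each pair left out in turn, Ccnd1 passed in 4 of 6 fits, Rbp4 in 3, Cryab and Egf in 2, and Dbp and Fabp3 in 1; S100a4 and Col1a1, measured in 4 pairs, could be tested in 2 of these fits and passed in 1 and 2.

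Several genes known from kidney injury varied widely between pairs. Spp1 (osteopontin) averaged 0.22 ± 0.77, Clu (clusterin) 0.21 ± 0.54 and Vim (vimentin) 0.19 ± 0.48 (each n = 6), with adjusted p of 0.65, 0.56 and 0.54. Pair C stood opposite to pairs A, E and F in all 3 genes, at -1.15, -0.69 and -0.64. Timp1, an inhibitor of matrix proteases, had 0.43 ± 0.23 (n = 4, adjusted p = 0.085). Umod, the urinary protein of the thick ascending limb, had -0.24 ± 0.13 with values below 0 in 6 of 6 pairs (adjusted p = 0.098). Agt (angiotensinogen) had 0.19 ± 0.20 (n = 6, adjusted p = 0.28) and Vegfa 0.12 ± 0.15 (n = 5, adjusted p = 0.49). Fn1, Kdr, Hmox1 and C3 had values in fewer than 4 pairs, and Klk1, Havcr1, Tgfb1, Ace, Edn1, Nos3 and Aqp2 were not analysed here.

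Lists of genes fixed in advance were compared with all other genes to see which groups had moved together. Of 16 lists with at least 3 measured genes, 7 passed the threshold with camera's preset correlation. Injury and repair genes were higher as a group at the preset correlation of 0.01 (mean 0.26, 13 of 14 means above 0, adjusted p = 0.00055). The correlation estimated from the members measured in every pair was 0.92, and with it the adjusted p was 0.43. The 8 members measured in every pair thus moved nearly as 1, and their number adds little to the number of pairs. S100a4, Lgals3 and Igfbp3 were not among them, and Igfbp3 was highest in pair C (0.69), so this does not cover the whole list. Only 1 member, S100a4, was past the threshold, both over all genes and adjusted over the list alone. The list mean was 0.30 with only sham in Cy3 and 0.15 with only sham in Cy5, and over the 14 genes themselves 0.34 and 0.15. Other members were Lgals3 with 0.47 ± 0.58 (n = 5) and Tmsb10 with 0.45 ± 0.47 (n = 6). The list median was above 0 in 4 of 6 pairs, from 0.71 in pair A to -0.37 in pair C, and between -0.10 and 0.19 on the sham-sham arrays. Matrix and fibrosis genes were also higher (mean 0.17, 9 of 14 above 0, adjusted p = 0.0051), but did not pass with an estimated correlation (adjusted p = 0.41) or with only sham in Cy3 (adjusted p = 0.086). Col1a1 and the basement membrane collagen Col4a1 (0.46 ± 0.19, n = 4) passed over all genes, and adjusted over the list alone 4 passed, with Timp1 and the proteoglycan Bgn (0.31 ± 0.23, n = 6). Without pair A, B, E or F the matrix list did not pass (adjusted p = 0.66, 0.10, 0.56 and 0.41). Only 7, 9, 7 and 7 of its 14 genes could then be tested. Col1a1, Col4a1 and Timp1, measured in these 4 pairs alone, were not among them. The mean was 0.0012 without pair A, 0.034 without E and 0.037 without F, against 0.054 for the same 7 genes over all pairs. It was 0.10 without B against 0.098 for the same 9 genes. Without pair A the injury list did not pass (adjusted p = 0.093), with a mean of 0.13. Without pair F its mean was 0.16, both over 13 genes whose mean over all pairs was 0.23. Macrophage and antigen presentation markers were higher (mean 0.17, 5 of 5 above 0, adjusted p = 0.012), with a list median above 0 in 6 of 6 pairs and no single member past the threshold. The adjusted p was 0.29 with an estimated correlation and 0.18 with only sham in Cy3. There 9 genes could be tested, with a mean of 0.10, and the 5 genes themselves had a mean of 0.21. RT1-Ba, a class II molecule, had 0.24 ± 0.27 (n = 6). The same list ranged from -0.27 to 0.35 on the sham-sham arrays, and it did not pass without pair A (adjusted p = 0.11), B (0.069) or F (0.090). In these fits 3 of its 5 genes could be tested, and the means were 0.16, 0.19 and 0.14, against 0.18 for the same 3 genes over all pairs.

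**Figure D2:**
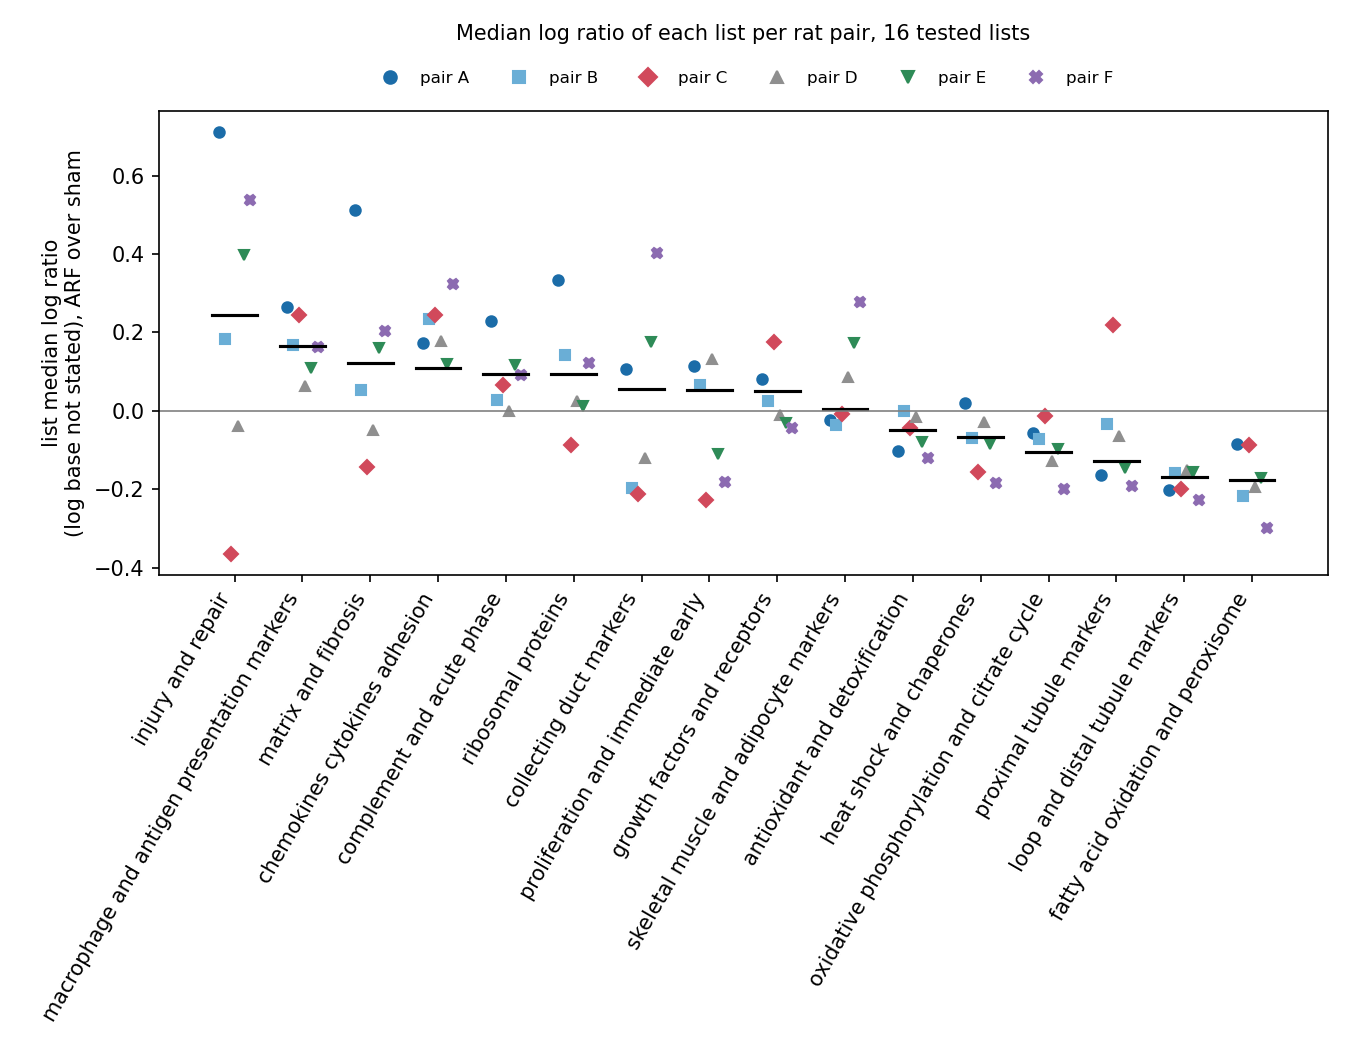
Median log ratio of ARF over sham (vertical axis, log units of unstated base) of each of the 16 tested lists in each rat pair; points are pairs and black bars are the median over genes of their mean log ratio. The fatty acid oxidation list and the loop and distal tubule list lay below 0 in all 6 pairs, and the injury list ran from 0.71 in pair A to -0.37 in pair C.

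Fatty acid oxidation and peroxisome genes were lower as a group (mean -0.15, 14 of 15 below 0, adjusted p = 0.00035), with the list median below 0 in 6 of 6 pairs. It did not pass with an estimated correlation (adjusted p = 0.29), and its median ran from -0.14 to 0.15 on the sham-sham arrays. Fabp3 passed over all genes, and adjusted over the list alone 4 fell: Fabp3, the trifunctional protein subunit Hadhb (-0.27 ± 0.20, n = 6), the acyl-CoA synthetase Acsl1 (-0.22 ± 0.13, n = 5) and the enoyl-CoA hydratase Echs1 (-0.19 ± 0.088, n = 6). Oxidative phosphorylation and citrate cycle genes were lower (mean -0.10, 16 of 18 below 0, adjusted p = 0.0044) with no member past the threshold, and did not pass with an estimated correlation (adjusted p = 0.29). Atp5pb, a subunit of ATP synthase, had -0.28 ± 0.23 (n = 6). Loop and distal tubule markers were lower (mean -0.15, 7 of 9 below 0, adjusted p = 0.025), below 0 in 6 of 6 pairs and between -0.032 and 0.047 on the sham-sham arrays. With an estimated correlation the list did not pass (adjusted p = 0.29). That correlation was 0.022, close to the preset 0.01, while the unadjusted camera p went from 0.011 to 0.058. The estimated setting also has fewer degrees of freedom, so the rise in p does not rest on member correlation alone. Egf passed over all genes, and adjusted over the list alone 4 fell: Egf, the kallikrein Klk1b3 (-0.44 ± 0.34, n = 6), the salt cotransporter Slc12a1 (-0.31 ± 0.22, n = 6) and Umod. The 2 members above 0 did not pass. They were Pvalb (0.12 ± 0.11, n = 6) and, named after its values were seen, Slc12a3 (0.12 ± 0.27, n = 5). The list did not pass without pair A (adjusted p = 0.093), B (0.073) or F (0.056), although its mean over the same 9 genes was then -0.15, -0.14 and -0.12. It did not pass with only sham in Cy3 either, where 11 genes had a mean of -0.081 (adjusted p = 0.21) and the 9 genes themselves -0.091.

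Ribosomal protein genes were higher as a group (mean 0.077, 26 of 30 above 0, adjusted p = 0.00055), with no member past the threshold. The adjusted p was 0.41 with an estimated correlation, and the list median lay above 0 on all 6 sham-sham arrays, from 0.026 to 0.24. Rps15a had 0.22 ± 0.14 and Rpl15 0.21 ± 0.12 (each n = 6). This list moved with the dye: 19 of its 30 genes had a dye effect past the threshold, its mean was 0.21 on the arrays with sham in Cy3 and -0.063 on those with sham in Cy5, and oxidative phosphorylation genes likewise turned from 0.012 to -0.22. Without pair A the ribosomal list did not pass (mean 0.025, adjusted p = 0.093). Under fry, which tests a list's own genes and used those measured in all 6 pairs, the adjusted p was 0.37 for injury and repair, 0.46 for matrix, 0.11 for macrophage markers and 0.18 for ribosomal proteins. The other 3 of the 7 lists passed, as did the chemokine list (0.016) and the heat shock list (0.030).

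The remaining 9 tested lists did not pass, although with only sham in Cy5 the proximal tubule and antioxidant lists did (adjusted p = 0.035 and 0.0067) and with only sham in Cy3 the chemokine list did (adjusted p = 0.040). Proximal tubule markers had a mean of -0.073 (14 of 21 below 0, adjusted p = 0.080), with Hao2 at -0.37 ± 0.27 (n = 5) and Cubn, the receptor cubilin, at -0.22 ± 0.20 (n = 6); without pair C, where the list median was 0.22, the mean was -0.13 and the list passed (adjusted p = 0.0046). Chemokines, cytokines and adhesion molecules had a mean of 0.15 over 3 genes (adjusted p = 0.063), of which the chemokine Cx3cl1 passed over all genes (0.24 ± 0.085, n = 6). Antioxidant genes had a mean of -0.059 (adjusted p = 0.085), with Sod2 at -0.17 ± 0.093 (n = 6), and passed without pair D (adjusted p = 0.016), and heat shock genes a mean of -0.14 (adjusted p = 0.096), in which Cryab passed. Proliferation genes had a mean of -0.088 and a camera statistic below 0 but a median of 0.053 (adjusted p = 0.64), and Ccnd1 passed. Collecting duct markers went both ways (adjusted p = 0.85): adjusted over the list alone, the kinase Sgk1 was higher (0.42 ± 0.35, n = 5) and the sodium channel subunit Scnn1a lower (-0.22 ± 0.10, n = 5). Growth factors (adjusted p = 0.68), complement and acute phase genes (0.64) and skeletal muscle and adipocyte markers (0.60) had means of 0.0091, 0.087 and 0.020. The 8 other lists had fewer than 3 measured genes: smooth muscle and podocyte markers had 2 each, endothelial and vasoactive genes 1 each, and the lymphocyte, apoptosis, erythrocyte and neuronal lists 0. The smooth muscle genes Tagln (0.41 ± 0.33, n = 5) and Tpm1 (0.18 ± 0.17, n = 6) passed when adjusted over their list alone.

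The sham-sham arrays were used to see which clones depart from 0 without an injury, by rat or by dye. Of 857 clones tested on the 6 sham-sham arrays, 24 passed the threshold, 7 above 0 and 17 below, and 200 had an unadjusted p under 0.05. This fit treats the 6 arrays as independent although they share rats, with sham rat F on 3 of them, so n counts arrays here and the p-values do not rest on separate animals. Singled out after their values were seen were the lipogenic enzyme Fasn (-0.59 ± 0.32, n = 6), the distal salt cotransporter Slc12a3 (-0.69 ± 0.49, n = 5) and the growth factor-binding protein Igfbp5 (-0.38 ± 0.20, n = 6), as channel 2 over channel 1. None of the 24 was among the 9 clones past the threshold for ARF against sham. So few calls on either side would seldom overlap in independent lists, so this says little. The sham rats reused on these arrays do not balance the dyes; without array R4 or R5 the limma count was 0 (138 and 152 at an unadjusted p under 0.05), without R3 it was 4 and without R6 it was 13.

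The spread of log ratios was compared to ask whether ARF and sham rats differ more than sham rats do. The SD over clones was 0.272 ± 0.029 on the 6 ARF-sham arrays with sham in Cy3 and 0.264 ± 0.075 on the 6 sham-sham arrays. The difference was 0.0079 (two-sided exact permutation p = 0.857, 924 permutations). Among the sham-sham arrays, R2 had 0.408 and the others 0.205 to 0.281. Taken with the sham-in-Cy5 arrays instead, the difference was 0.036 (two-sided exact permutation p = 0.30). As a median absolute deviation in place of the SD it was 0.023 (two-sided exact permutation p = 0.41). Over the 318 clones with values on all 18 arrays, the ARF-sham arrays spread more by 0.057 (two-sided exact permutation p = 0.0087). The arrays share sham rats, and these tests treat them as independent, so no p given here can be read as the chance of such a difference. Spot noise also enters the spread over clones. Duplicate spots differed with an SD of 0.128 to 0.18 on the arrays with sham in Cy3. On the sham-sham arrays this SD was 0.129 to 0.217, highest on R2. A larger spread between ARF and sham rats could be hidden by such noise.

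The dye effect passed the threshold for 152 of 947 clones, 99 higher in Cy5 and 53 higher in Cy3 under the assumed direction. It was 0.22 ± 0.046 for the metallothionein Mt2A, 0.20 ± 0.039 for the superoxide dismutase Sod1 and 0.21 ± 0.038 for the cytochrome oxidase subunit Cox5b (each n = 6), 3 genes picked after their values were seen. Of 668 clones tested in both, 6 passed for the dye effect and between sham rats, against 3.26 for independent lists, and all 6 had the same sign. The count was 73, 55 and 61 without pairs C, D and E.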

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

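The search for a pair or array far from the others ran on 102 groups of values, of which chance alone would pick about 5.1, and it picked 6. In every case 1 value lay apart by Dixon's criterion.

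Array R2, of sham rats A and E, had an SD of 0.408 over clones, against 0.205 to 0.281 on the other sham-sham arrays. Apoe was at -0.48 in pair B and between 0.22 and 0.50 in the other 5 pairs. Col4a1 was at 0.17 in pair B and between 0.53 and 0.58 in the other 3 pairs that measured it. Pair A stood apart for Car2, at 0.30 against -0.34 to -0.17, for Hadhb, at 0.13 against -0.42 to -0.27, and for Suclg1, at 0.067 against -0.27 to -0.17. No explanation was tested for these values.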

How the results depend on the processing

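Alternatives chosen after the data were seen were the single spots, the centring per block of rows, the deposited row order, and for lists the single orientations and left-out pairs. The count of 9 clones for ARF against sham became 42 with the pair as a replicate block over 12 arrays, 29 with a dye term added to it, and 3 of 565 with no replicate block (12 rat levels). It became 0 with the unmoderated test and 0 with trend and robust, 16 centred on the median and 16 also scaled, 5 with pairs of 1 array kept, 15 per gene symbol, 28 with only the sham-in-Cy3 arrays, 23 for single spots and 5 centred per block of rows; without 1 pair it ran from 0 to 19. Of the 9 clones, 9 passed with the block and 8 with the dye term. These fits reuse the same arrays and count the 2 arrays of a pair in part as separate, so this is no independent support. The spread difference passed on clones with all 18 arrays (0.057, exact permutation p = 0.0087, over arrays that share rats). The sham-sham count of 24 ran from 0 to 32 without 1 array, and the dye count of 152 from 55 to 175 without 1 pair. The 7 lists became 0 with an estimated correlation, which also used fewer degrees of freedom, and 4 with only sham in Cy3, and 2 to 8 without 1 pair. The causes of these differences were not tested; fewer clones were tested without a pair.

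Signs turned in values that were not past the threshold, apart from 2 lists. With only sham in Cy3, Cox6c was 0.017, Crp 0.038, Hspb6 0.017, Hspe1 0.031, Lpl -0.13, Stmn1 -0.042 and Vegfa -0.035, and the list means were 0.012 for oxidative phosphorylation and 0.016 for antioxidants; for collecting duct only the camera statistic turned, at a mean of 0.056 against 0.053. With only sham in Cy5, Ccnd2 was 0.034, Mif -0.048, Odc1 -0.048, Pdia3 0.091, Rplp0 -0.0041, Rps23 -0.020 and Thy1 0.015, and ribosomal proteins had -0.063. Ptpro was 0.0035 centred on the median and 0.0031 centred per block; growth factors had -0.020 under fry. Without 1 pair Il6r ran from -0.022 to 0.20 and the collecting duct mean from 0.0077 to 0.12, its camera statistic turning. The cause was not tested. The 8 named genes past the threshold kept their sign in 139 of 139 gene and alternative combinations and their side of the threshold in 80. Many of these signs could not turn. Each gene had been named for 1 sign in every measured pair, so leaving out a pair could not change it, and several settings keep the same mean. Exact zeros as missing and the conversion of the log base were not run, since no value was 0 and the base is unknown.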

Other observations

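The tests on row order and on pair C were chosen after the results were seen, as was the count of clones kept under dye subtraction, while the splits and the other tests on the sham-sham calls were fixed before. With 1 value per gene symbol, 15 of 680 genes passed. Besides the 8 genes above these were St6gal1, Col4a1 and Cx3cl1, and, named after their values were seen, Ltbp4 (0.52 ± 0.25, n = 4), a matrix protein that binds latent TGF-beta, the transcription factor Nr2f2 (0.26 ± 0.10, n = 6), Unc119 (-0.33 ± 0.18, n = 6) and Nr1d1 (-0.38 ± 0.10, n = 4), a transcriptional repressor.

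Pair C lay below the mean of the other pairs in injury genes, with a median distance of -0.848 over 12 genes. The list median was -0.37 in pair C, -0.038 in pair D and above 0 in the other 4, while S100a4 (0.36) and Igfbp3 (0.69) were above 0 in pair C. Its clones correlated at -0.157 with the mean of the other pairs, against 0.161 to 0.776 for each of the other pairs. Taken 2 at a time, the pairs had a median r of 0.134. The lowest value was that of A and D (-0.227), below A and C (-0.197), so the other pairs did not all move together either. Higher injury genes in sham rat C were argued against by the array of sham C and sham F, where the median absolute value of these genes was 0.134. Had the 2 rats of pair C been exchanged on every array, this array would hold ARF rat C. The same value therefore bears on that exchange as well, but it comes from 1 array. An exchange confined to the 2 arrays of pair C is not touched by it and stays open. Of 125 clones with 1 sign in the other 5 pairs, 53.6% had the opposite sign in pair C. Taken in the same way, the shares were 40.2%, 28.4%, 29.3%, 13.4% and 3.33% for pairs A, B, D, E and F. Of the 14 clones that passed without pair C and were measured in it, 7 were opposite. Ccnd1, Cryab and Egf were below 0 there as in the others. They were named from a fit that included pair C and for having 1 sign in every measured pair, so their agreement does not bear on an exchange. A different share of cortex may also contribute, though the labels say total kidney. Proximal tubule genes lay 0.418 above the other pairs, and the pooled loop, distal and collecting duct genes at -0.179. This gap was larger than in 100% of 10000 random lists. The estimated correlation was 0.40 for proximal, 0.26 for collecting duct and 0.022 for loop and distal markers. Random lists need not share such correlation, so the 100% cannot be read as the chance of such a gap. Collecting duct genes alone lay at -0.479, but loop and distal genes alone at 0.0749. A milder injury of ARF rat C was not tested.

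The sham-sham arrays held values on other rows than the ARF-sham arrays. Fewer spots passing the filter is argued against by the correlation of filled cells, -0.011 on the rows as deposited. An exchange of adjacent blocks of rows is consistent with 34 of 36 combinations of sham-sham array and pair having a dye correlation above 0 after it, against 23 as deposited; the mean correlation went from 0.0275 to 0.171. No biological explanation was tested.

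More clones passed between sham rats, 24, than between ARF and sham rats, 9, but the 24 come from a fit that treats arrays sharing rats as independent and the 9 from 6 pairs of separate rats, so the 2 counts are not on the same footing. The dye effect stays open as a source. With its mean subtracted 27 clones passed, against 26 over the same clones without subtraction, and the bound set in advance on this count would have counted against the dye. That bound was wrong, because a count does not say which clones: 9 of the 26 were above 0 and 0 of the 27, and 12 of the 26 were kept. Real differences between sham rats reused in 1 channel cannot be told apart from other sources: the sign predicted from the pairs matched the call in 71.4% of 14 called clones, against 61.1% of all tested clones, and the arrays are too few to separate rats from dye.

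Turning the sign of pairs gave 32 splits. For ARF against sham, 2 of the 32 splits gave at least 9 calls, the real one included, and the highest other gave 15, with pair C turned, so chance is not excluded. For lists 2 of 32 gave at least 7, and the highest other gave 8, with pair D turned, so chance is not excluded there either. For the dye effect 1 of 32 gave 152 and the highest other 0. This is the smallest share that 32 splits can give, so chance is unlikely there but not excluded. Between sham rats 1 of 32 gave 24 and the highest other 1, but these arrays share rats, so their signs do not turn independently and the splits decide nothing about chance.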
